A study of Homo sapiens with 192 samples.

How the data were processed

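The data are RNA sequencing libraries of synovial fibroblasts grown from 4 donors. Per the labels' protocols, cells were transfected with an siRNA and plated at 50000 cells per well in 24-well plates, moved to medium with 1% serum on the next day, and stimulated on the day after. RNA was purified and polyadenylated RNA was amplified by the Smart-seq2 method, which makes full-length cDNA and keeps no strand, per the labels' protocols. The labels give 192 libraries: 6 siRNAs in 7 conditions, with 4 donors in each of the 42 groups and 2 wells per donor and siRNA in the unstimulated groups. The doses, TNF at 0.1 ng/mL and IL-17A at 1 ng/mL, are those of the treatment protocol.

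Reads were quantified with kallisto 0.43.1, per the submitters' processing notes, and the genome build and annotation are not given in the sources used here. The authors deposited estimated counts per gene (31733 genes), estimated counts per transcript (150537 transcripts) and TPM, transcripts per 1000000 transcripts, per gene (28888 genes). The deposited estimated counts were not scaled to depth, while each library of the deposited TPM table sums to just under 1000000. Estimated counts per gene equalled the sums over their transcripts within 0.01 for 31388 of the 31646 genes that could be compared. Y-linked genes, XIST and TSIX were removed at the start (246 genes), which left 31487. Gene symbols came from a reference table of gene names for 31525 genes and from GENCODE release 29 for 128, and 80 genes had none. The list genes PPBP, S100A9 and CD3D had no values in the count table.

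Libraries under 1000000 estimated counts were left out of all main tests. That removed 3 libraries: control siRNA with TNF+IL-17A at 16 h in donor 1 (329 counts), STAT4 siRNA with TNF at 16 h in donor 2 (25300 counts) and 1 of the 2 unstimulated wells with STAT3 siRNA in donor 2 (110606 counts). The design had named all 192 libraries, so this is a departure from it, and the tests were also run on all 192. The 189 libraries used held 1979397 to 8908418 estimated counts (median 5049378). No molecular identifiers were used, so counting intervals and floors cover counting error only. Per library, a median of 1.05% of counts was mitochondrial (range 0.41% to 4.92%). Libraries whose root mean square residual over genes, in a fit of log2 CPM (counts per 1000000 counts) on group and donor, was over 1 are said to stand apart: there were 5, and the others had a median of 0.466. Of the 5, 4 came from donor 2, of which 3 had STAT3 siRNA (TNF at 1 h and TNF+IL-17A at 1 and 16 h, with 4.26%, 2.64% and 4.44% of counts mitochondrial) and 1 STAT4 siRNA (unstimulated, 4.92%). The other 4 used libraries of donor 2 with STAT3 siRNA had 1.82% to 2.44%. The fifth was the control siRNA library of donor 3 with TNF+IL-17A at 16 h (2.28%). Median totals per siRNA ran from 4445312 (ELF3 siRNA) to 5465650 (control siRNA).

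The labels state the donor of each library, so the donor was a block in every test. Residuals of libraries after removal of the group means were correlated with a median of 0.51 within a donor (0.44 to 0.54 per donor) and -0.27 between donors. Donors 3 and 4 lie on plate 1 and donors 1 and 2 on plate 2, and the block absorbs this plate with the donor. Culture plates within a donor are unlabelled and not absorbed. No libraries had identical columns, and paired unstimulated wells differed by more than counting error, with an index of dispersion of at least 4.83 against 27.3 or more between donors.

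Counts of the paired unstimulated wells were summed, which gave 166 columns. The response to TNF, the effect of IL-17A in control cells, the siRNA effects at 6 h of TNF+IL-17A and the changes of the IL-17A effect were tested with the quasi-likelihood test of edgeR 4.0.16 on rounded estimated counts. The fit held all 42 groups and the donor, with TMM scaling, robust dispersion and the filterByExpr filter at a minimum count of 10, which kept 15038 genes. It takes the wells of a donor and siRNA as independent although they share a transfection, so its p values for siRNA effects can be too small. A change of the IL-17A effect is the TNF+IL-17A minus TNF difference under an siRNA, minus that under control siRNA, averaged over 6 and 16 h. Mean siRNA effects were tested with limma 3.58.1 (trend and robust options) on log2 CPM with a prior count of 2. These values were averaged with equal weights over the 7 conditions per donor and siRNA, which gave 24 columns, or over the 6 siRNAs per donor and condition for the mean effect of IL-17A, which gave 28 columns. Where a library was left out, these means used only what both sides of a comparison had: 6 conditions for the siRNA means of donors 1 and 2, and 5 siRNAs for the IL-17A mean at 16 h in those donors. P values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Levels are log2 CPM with the same prior count. Donor counts such as 4 of 4 compare log2 CPM within each donor. Where a group had 0 counts the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with its 95% counting interval.

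The 24 comparisons, the gene lists and the rule for the genes named were fixed before the data were examined. Under that rule a gene is named when it passes, changes in the same direction in all donors, has a symbol that is not a clone or locus name, and is among the 10 largest rises or falls of a comparison. The number is 8 for the mean siRNA effects and 5 for siRNA effects at 6 h of TNF+IL-17A and for changes of the IL-17A effect. Up to 4 members of each gene list and, in every comparison, a fixed panel of 14 genes and the 5 targets were added. The 25 gene lists were tested in all 24 comparisons with camera of limma at its preset inter-gene correlation of 0.01, adjusted over all 600 tests, and again with an estimated correlation.

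Alternatives planned in advance were RLE scaling, no low-count filter, no donor block, leaving out each donor, the donors of each plate alone, limma on log2(TPM + 1), edgeR and DESeq2 1.42.0 on the compared groups alone, unstimulated wells kept separate, counts summed per donor, a prior count of 0.5, the 6 stimulated conditions alone, and a fit of only the siRNA and the control. A further 5 were added after the data were seen: all 192 libraries, no libraries that stand apart, removal of each library's trend on GC content and transcript length (lowess span 0.3, GENCODE release 29 transcripts), each siRNA against the mean of the other 4, and adjustment of the target tests over the 35 alone.

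The tests were tested on simulated counts with 200 changed genes among 14604. For TNF at 6 h the edgeR test recovered 56% of 2-fold and 96% of 4-fold changes, with 2 false calls among 154. For the change of the IL-17A effect under STAT4 siRNA it recovered 53% and 91%, with 14 false calls among 209. The limma test of the mean effect of STAT3 siRNA recovered 98% and 100%, with 13 false calls among 228, and that of IL-17A at 6 h 97% and 100%, with 17 among 260. Simulated wells of a donor shared only a donor effect, so a deviation shared by the wells of a donor and siRNA was not covered. The shares recovered by these limma tests need not hold for the data. On the compared groups alone, with 12726 genes, edgeR recovered 35% and 90% and DESeq2 58% and 95%, the latter with 33 false calls among 186. Calculations used R 4.3.3 with data.table (1.17.8) and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.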

Results

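The libraries measured polyadenylated RNA of synovial fibroblasts, the connective tissue cells of the joint lining, grown from 4 donors. The labels name each of these donors by the letters RA and a number. The cells of each donor were given 1 of 6 small interfering RNAs (siRNAs): a control siRNA, or an siRNA against CUX1, LIFR, STAT3, STAT4 or ELF3. They were then left unstimulated, or were stimulated for 1, 6 or 16 h with the cytokine TNF at 0.1 ng/mL, alone or together with the cytokine IL-17A at 1 ng/mL. This made 42 groups of 4 donors and 192 libraries, with 2 wells per donor and siRNA in the unstimulated groups and 1 in the others. The study asks which of these regulators carry the response of synovial fibroblasts to TNF and IL-17A. All but 3 of the libraries were used, and these held 1979397 to 8908418 estimated counts, with a median of 5049378 and a median of 16243 genes detected. The 3 left out had 329, 25300 and 110606 counts, so the control siRNA group at 16 h of TNF+IL-17A and the STAT4 siRNA group at 16 h of TNF rested on 3 donors. The median total was lowest with TNF+IL-17A at 1 h (3285914) and highest with TNF at 16 h (5973830).

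The targeted genes were read first, as a check of the labels. CUX1, LIFR, STAT3 and STAT4 transcripts were lower in the cells given the siRNA against them, and ELF3 transcripts were not shown to be lower than in control cells in the mean over conditions. In the mean over the 7 conditions, STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388568), a transcription factor used by cytokines of the IL-6 family, had 4.68% of its control level left (log2 fold change -4.42 ± 0.24 SE, limma adjusted p = 1.1e-09, lower in 4 of 4 donors). CUX1 (ENSG00000257923, chromosome 7, 101815904 to 102283958), a homeobox transcription factor, had 10.6% left (-3.24 ± 0.28, limma adjusted p = 5.2e-07). LIFR (ENSG00000113594, chromosome 5, 38474963 to 38608354), the receptor of leukaemia inhibitory factor, had 14.9% left (-2.74 ± 0.20, limma adjusted p = 7.8e-08). STAT4 (ENSG00000138378, chromosome 2, 191029576 to 191151596), a transcription factor of cytokine signalling that was low in these cells, had 22.6% left (-2.14 ± 0.31, limma adjusted p = 2.4e-04), and these 3 genes too were lower in 4 of 4 donors. ELF3 (ENSG00000163435, chromosome 1, 202007945 to 202017188), a transcription factor of the ETS family, was at -0.41 ± 0.83 log2 CPM (counts per 1000000 counts) in unstimulated control cells (SD, n = 4) and at 3.03 ± 1.38 after 6 h of TNF+IL-17A. Its level under ELF3 siRNA differed from control by less than the test could resolve at 6 h of TNF+IL-17A (-0.96 ± 0.60, 51.5% left, edgeR adjusted p = 0.50, lower in 3 of 4 donors) and at 16 h (-1.60 ± 0.68, 33.1% left, edgeR adjusted p = 0.196, lower in 2 of 3 donors). Of the 35 tests of a target in 1 condition, 24 passed with the edgeR quasi-likelihood test over all genes and 29 when adjusted over the 35 alone, among them ELF3 at 16 h of TNF+IL-17A (0.0237). Against the mean of the other 4 targeting siRNAs, a comparison added after the data were seen, ELF3 was lower under its own siRNA (-0.69 ± 0.15, limma adjusted p = 0.0157). Most of that difference was its higher level under the others: against control it was at 0.34, 0.49, 0.70 and 0.75 under CUX1, LIFR, STAT3 and STAT4 siRNA, and at -0.12 under its own. Positions are those of GENCODE release 29 on GRCh38.

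**Figure D1:**
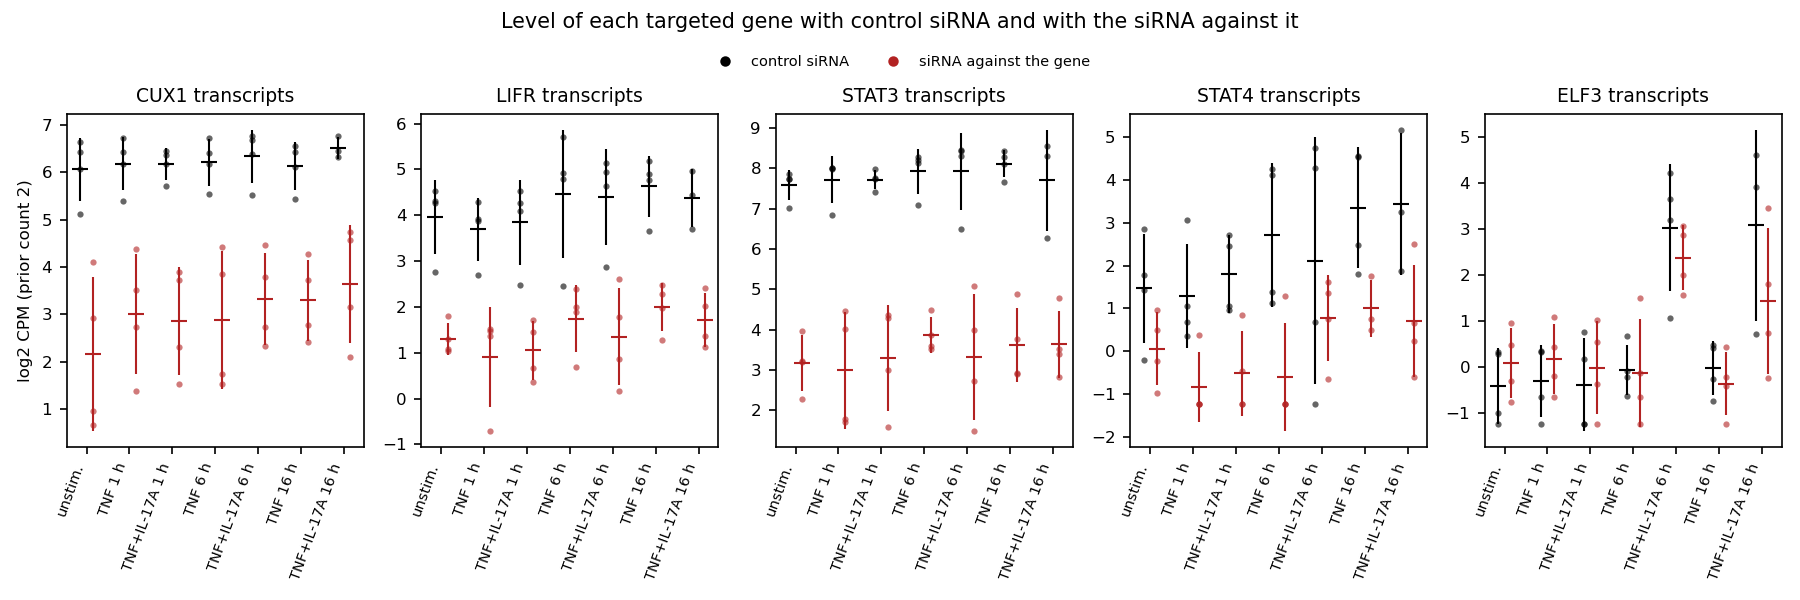
Levels of the 5 targeted genes (log2 CPM, y axes) in each condition (x axes) with control siRNA (black) and with the siRNA against the gene (red); points are donors, and bars mark the mean and SD. STAT3 had 4.68% and CUX1 10.6% of the control level left in the mean over conditions. In control cells the mean of ELF3 was 3.03 and 3.08 with TNF+IL-17A at 6 and 16 h, and from -0.41 to -0.03 in the other conditions.

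TNF alone was compared with no stimulation in control siRNA cells to show the response that the siRNAs were tested on. After 1 h, chemokines that attract neutrophils led the rise: CXCL8 went from -0.49 ± 0.38 to 6.97 ± 0.95 log2 CPM (SD, n = 4). CXCL3, CXCL2 and CXCL1 rose by 8.80 ± 0.64, 8.16 ± 0.66 and 7.84 ± 0.64 on the log2 scale (± is from here the SE of a log2 fold change). The feedback inhibitors of NF-kB signalling TNFAIP3 (6.28 ± 0.47) and NFKBIA (5.39 ± 0.43), the orphan nuclear receptor NR4A1 (5.45 ± 0.64), the cytokine LIF (5.38 ± 0.46), the transcription factor IRF1 (5.14 ± 0.48), the adhesion molecule ICAM1 (5.03 ± 0.39) and IL6 (3.45 ± 0.41) rose with them. CCL20, a chemokine for lymphocytes and dendritic cells, had 3 counts over the unstimulated group, and its ratio was 256 (95% counting interval 87 to 1250). For the cytokine genes CSF2 and TNF the counting intervals of the ratio were 54.8 to 790 and 50.1 to 723. The test passed 180 genes, 8 of them lower. The 8 were PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1 (-2.19 ± 0.38), KCNE4, DDIT3, TXNIP, ITFG2, TSC22D3, ZNF564 and ZNF555, down to -0.87 ± 0.23 for TSC22D3. Of the gene lists, 14 of 21 genes of NF-kB signalling and feedback rose (15 adjusted over the list alone; camera adjusted p = 8.9e-110), as did 16 of 22 immediate early genes (18 adjusted over the list alone; 2.5e-73) and 5 of 6 chemokines of the CXC family with an ELR motif (5 adjusted over the list alone; 1.2e-88). None of the genes on these lists fell. The matrix-degrading enzyme genes MMP1 (1.30 ± 0.44, adjusted p = 0.226) and MMP3 (1.07 ± 0.79, adjusted p = 1.00) did not pass at this time.

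After 6 h of TNF, CXCL10, which attracts T cells, had 13696 counts against 1 over the unstimulated group, a ratio of 28800 (5180 to 1140000). It had also passed at 1 h, with 75 counts (23.3 to 5360). Its relatives CXCL11 and CXCL9, at 0 counts unstimulated, were at least 541-fold and 211-fold higher, against a floor of 3 counts over the group. IDO1, an enzyme that breaks down tryptophan (9.27 ± 1.15), CD274, the ligand of an inhibitory receptor of T cells (7.77 ± 0.71), and RSAD2, an antiviral protein (7.62 ± 1.11), rose too. In all 26 of 27 interferon response genes passed (27 adjusted over the list alone; camera adjusted p = 2.6e-65). CXCL8 had its highest level with TNF here, 8.01 ± 0.92 log2 CPM (SD, n = 4). MMP1 rose by 5.10 ± 0.51 and MMP3 by 3.03 ± 0.77, and the superoxide dismutase SOD2 and the complement factor CFB rose by 3.93 ± 0.28 and 4.16 ± 0.36. Among the falls were ANGPTL4, an inhibitor of lipoprotein lipase (-4.22 ± 0.48), GDF5, a growth factor of joint tissue (-3.81 ± 0.36), TOX (-3.78 ± 0.63), FMO2 (-4.04 ± 1.12) and RASL11A (-3.78 ± 0.92). HS3ST1, INSYN2B and TAS1R1 had 0 counts at 6 h and were at least 6.33-fold, 5.86-fold and 3.64-fold lower. In total 1037 genes were higher and 480 lower. All 6 ELR CXC chemokines, 13 of 14 other chemokines and 19 of 21 genes of NF-kB signalling rose (6, 13 and 20 adjusted over each list alone). Of the immediate early genes 7 of 22 rose and 2 fell, FOS among them (-2.63 ± 0.58), and that list did not pass (camera adjusted p = 0.0932).

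After 16 h of TNF, 697 genes were higher and 412 lower. All 27 interferon response genes rose (27 adjusted over the list alone; camera adjusted p = 1.7e-73), with CXCL10 at a ratio of 4700 (843 to 186000) to its unstimulated level. MMP1, an interstitial collagenase, rose by 6.28 ± 0.54, MMP3 by 3.76 ± 0.77 and the chemokine CCL5 by 7.58 ± 0.77. IL6 rose by 4.32 ± 0.43, the cytokine IL32 by 5.16 ± 0.38 and the complement gene C3 by 2.52 ± 0.32, and the acute-phase gene SAA1 had a ratio of 354 (62.9 to 14100). Of the zinc transporters and metallothioneins, 11 of 15 rose (13 adjusted over the list alone; camera adjusted p = 1.1e-16), among them SLC39A8 (5.65 ± 0.43) and MT2A (2.92 ± 0.55). A further 4 of 16 complement genes rose (4 adjusted over the list alone; 6.3e-05). Of the cholesterol synthesis genes 5 of 21 rose, such as HMGCS1 and LSS (8 adjusted over the list alone; camera adjusted p = 3.9e-04), with adjusted p = 0.277 with an estimated correlation. STAT4 rose by 1.91 ± 0.62 (adjusted p = 0.0352). The falls included the urea transporter SLC14A1 (-3.61 ± 0.31), the oxidising enzyme CYP1A1 (-4.65 ± 1.01), the transporter ABCA8 (-4.39 ± 0.74), FOS (-2.59 ± 0.57) and the metalloproteinase inhibitor TIMP3 (-1.30 ± 0.18). All p values of single genes in these 3 comparisons are adjusted p values of the edgeR quasi-likelihood test with the donor as a block. Without donor 4 the counts at 1, 6 and 16 h were 91, 731 and 572 genes, and at 16 h they were 725 without donor 1 and 738 without donor 3. Of the 63 named genes that had passed in the 3 comparisons, 44 kept their call and direction whichever donor was left out. The falls DDIT3, TXNIP, ITFG2, TSC22D3, ZNF564, ZNF555, FMO2, RASL11A, HS3ST1, INSYN2B, TAS1R1, CYP1A1, VWF and CDH5 and the rises of HMGCS1, LSS, STAT4 and TEK at 16 h and of MMP3 at 6 h did not.

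The effect of adding IL-17A was read as TNF+IL-17A against TNF at the same time in control siRNA cells. At 1 h, edgeR passed 0 genes, with 265 at an unadjusted p under 0.05 (limma on log2(TPM + 1) and edgeR and DESeq2 on the compared groups alone passed 0 as well). NFKBIZ, a co-activator of NF-kB target genes, gave 0.59 ± 0.36. At 6 h, 8 genes rose and 0 fell, with 360 at an unadjusted p under 0.05. The largest was ELF3 (4.15 ± 0.77, edgeR adjusted p = 0.0017). With it rose the ELR CXC chemokines CXCL2 (2.74 ± 0.48), CXCL1 (2.56 ± 0.49), CXCL3 (2.33 ± 0.44) and CXCL8 (1.98 ± 0.45, adjusted p = 0.035), IL6 (1.95 ± 0.38), ZC3H12A, an RNase that degrades cytokine transcripts (1.87 ± 0.36), and RGS3, a regulator of G protein signalling (1.12 ± 0.21), each in 4 of 4 donors. CXCL1 reached 9.73 ± 0.90 log2 CPM with both cytokines, against 7.18 ± 0.80 with TNF (SD, n = 4). The growth factor of granulocytes CSF3 had 0 counts with TNF and 59 with both, at least 17.7-fold more, and did not pass (adjusted p = 0.155). Of the genes known to respond to IL-17A, a list fixed in advance, 7 of 22 rose (12 adjusted over the list alone; camera adjusted p = 1.9e-43). MMP1 (0.83 ± 0.43), MMP3 (1.57 ± 0.67), LIF (0.46 ± 0.37) and ICAM1 (-0.26 ± 0.33) did not pass. Without donor 1 the test passed 5 genes, without donor 3 it passed 0 (379 at an unadjusted p under 0.05), and without donor 4 it passed 1. On the compared groups alone edgeR passed 24 and DESeq2 35.

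At 16 h, the comparison in control siRNA cells rested on 3 donors with TNF+IL-17A. CXCL1 rose by 3.93 ± 0.54, CXCL3 by 3.66 ± 0.51, CXCL2 by 3.38 ± 0.53 and CXCL6 by 2.34 ± 0.44, each in 3 of 3 donors. The acute-phase gene SAA2 rose by 3.71 ± 0.90, CCL20 by 3.77 ± 0.72, ELF3 by 3.85 ± 0.78, IL6 by 2.19 ± 0.40 and the mitochondrial protein C15orf48 by 5.05 ± 0.78, each in 3 of 3 donors. CSF3, with 0 counts with TNF, was at least 25.9-fold higher. Of the IL-17A-associated genes 14 of 22 rose (16 adjusted over the list alone; camera adjusted p = 2.8e-26). Of the zinc and metallothionein genes 5 of 15 rose (9 adjusted over the list alone; 8.8e-07, and 0.00443 without the 5 libraries that stand apart), MT2A by 3.95 ± 0.59 (0.18 without donor 3 and 0.23 without those 5 libraries). The largest falls were those of the melanocortin receptor accessory protein MRAP2, with 0 counts and at least 4.39-fold lower, PLD6 (-2.04 ± 0.55), TMEM119 (-1.42 ± 0.43) and CD83 (-1.37 ± 0.36). In all, edgeR passed 461 genes higher and 26 lower. Of the 3 control libraries with TNF+IL-17A at this time that of donor 3 stood apart, with a root mean square residual of 1.01 against a median of 0.466 for the others. The median log2 change of the 461 genes was 2.84 in donor 3 and -0.02 and 0.02 in donors 2 and 4. Mitochondrial transcripts moved with it: 5 of 13 rose (7 adjusted over the list alone; camera adjusted p = 0.00139, adjusted p = 0.622 with an estimated correlation), and MT-ND3 (3.05 ± 0.62) was higher in 1 of 3 donors and gave -0.53 without the 5 libraries that stand apart, this one among them. Without those 5 edgeR passed 10 genes, all of them higher: CXCL1, CXCL2, CXCL3, CXCL6, IL6, ELF3, C15orf48, ZC3H12A, NAMPT and SLC11A2. Of the 16 called genes given above with a change, only CXCL1 kept its call whichever donor was left out. Without donor 3 edgeR passed 2, CXCL1 and ZC3H12A, without donor 2 it passed 1651. On the compared groups alone it passed 0 (278 at an unadjusted p under 0.05) and DESeq2 13, while limma on log2(TPM + 1) called 30 higher and 715 lower.

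**Figure D2:**
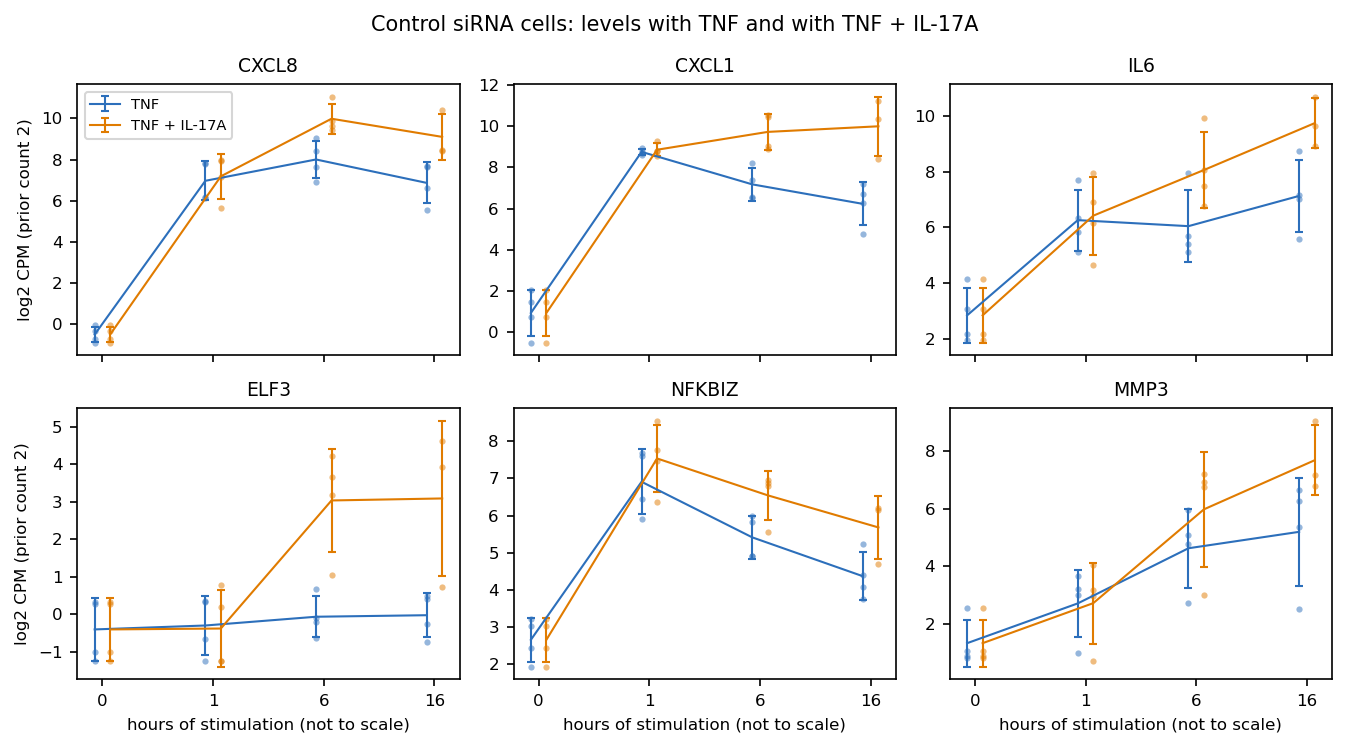
Levels of 6 genes (log2 CPM, y axes) against the time of stimulation (h, x axes, not to scale) in control siRNA cells, with TNF (blue) and with TNF+IL-17A (orange); points are donors, lines join the means, and bars mark the SD. CXCL1 reached 9.73 ± 0.90 with both cytokines at 6 h and 7.18 ± 0.80 with TNF. The mean of ELF3 was -0.31, -0.07 and -0.03 with TNF at 1, 6 and 16 h.

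The same effect was also averaged over the 6 siRNAs of a donor, or over 5 in donors 1 and 2 at 16 h, where a library was left out. At 1 h, limma passed 0 genes, with 607 at an unadjusted p under 0.05 (edgeR on counts summed per donor and limma on log2(TPM + 1) passed 0, and limma passed 1 without donor 4 and 1 without the low-count filter). At 6 h 14 genes rose and 0 fell, with 540 at an unadjusted p under 0.05, and edgeR on counts summed per donor called 15 higher and 0 lower. ELF3 (2.87 ± 0.35), CXCL2 (2.24 ± 0.33), CXCL1 (2.18 ± 0.36), CXCL3 (1.98 ± 0.29), CXCL6 (1.46 ± 0.24), IL6 (1.56 ± 0.26) and ZC3H12A (1.55 ± 0.26) rose in 4 of 4 donors. So did MFSD2A, a lipid transporter (1.61 ± 0.21), and GPR37L1 (1.31 ± 0.26). At 16 h CXCL1 rose by 3.47 ± 0.36, CXCL6 by 3.06 ± 0.24, CXCL2 by 2.80 ± 0.33, CXCL3 by 2.68 ± 0.29 and CXCL8 by 2.41 ± 0.32. IL6 (2.13 ± 0.26), CCL20 (2.24 ± 0.50), the hormone STC1 (1.88 ± 0.55) and the prostaglandin synthase PTGS2 (1.21 ± 0.22) rose too. All 6 ELR CXC chemokines rose (6 adjusted over the list alone; camera adjusted p = 6.3e-19), as did 13 of 22 IL-17A-associated genes (17 adjusted over the list alone; 1.8e-23) and 7 of 15 zinc and metallothionein genes (10 adjusted over the list alone; 2.4e-08). More genes fell than rose: 208 were higher and 746 lower. Among the falls were the immediate early genes JUNB (-1.81 ± 0.28), IER2 (-1.48 ± 0.28) and DUSP1 (-1.35 ± 0.26) and the desaturase FADS2 (-1.71 ± 0.24). The kinase DAPK3 (-1.86 ± 0.14), the adaptor of toll-like receptors TICAM2 (-1.83 ± 0.22), the metalloproteinase MMP11 (-1.49 ± 0.26) and SREBF2, which controls cholesterol synthesis (-1.15 ± 0.13), fell as well. Of the cholesterol synthesis list 3 of 21 fell (3 adjusted over the list alone; camera adjusted p = 0.00495), with adjusted p = 0.684 with an estimated correlation. Only 1 of 13 mitochondrial transcripts rose, MT-CO3 (0.29 ± 0.09; 6 adjusted over the list alone). The split at 16 h moved with the scaling, to 400 higher and 615 lower with RLE, 429 and 629 with the GC content and length trend removed, and 64 and 1248 with limma on log2(TPM + 1). Without donors 1, 2, 3 or 4 the counts were 5, 3, 2 and 6 genes at 6 h, ELF3 in each of them, and 1592, 549, 433 and 417 at 16 h, where CCL20, STC1, DUSP1 and MT-CO3 did not keep their call without every donor.

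The siRNAs were each compared with the control siRNA, to show which genes differed under each of them. This was done first in the mean over the 7 conditions and then at 6 h of TNF+IL-17A. Whether a difference came through the targeted gene was not tested. The 5 comparisons share the control libraries. In the mean over conditions 68 genes were higher and 3 lower under each of the 5 siRNAs. COL15A1, CELF2, LOXL3, LMLN, DDAH1, H2BC12 and TIMP3 were among the 68, and such genes were also the largest rises of most of the siRNAs. Their median log2 fold change over the 5 siRNAs was 0.88, with a range of 0.54 to 2.13. In 50 simulated data sets in which no siRNA had an effect and noise was independent between genes, 0 genes were called under all 5. Shared calls were rare in such data for any pair of siRNAs, so this 0 is no measure for lists of real calls.

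Under CUX1 siRNA the largest fall was that of PRG4, the joint lubricant of synovial lining cells, to a fold of 0.0134 of its control level (-6.22 ± 0.22, limma adjusted p = 2.2e-13). The serine synthesis enzyme PHGDH (-2.12 ± 0.16), HTATIP2 (-2.12 ± 0.19), the tight junction protein CLDN1 (-1.94 ± 0.24), LEPROT (-1.82 ± 0.10) and the interferon-induced genes IFI35 (-1.86 ± 0.25) and USP18 (-1.78 ± 0.26) fell too. The chemokines with an ELR motif fell: 5 of 6 passed (5 adjusted over the list alone; camera adjusted p = 8.8e-07, and 0.0439 with an estimated correlation), with CXCL1 at -1.52 ± 0.28, CXCL6 at -1.43 ± 0.23 and CXCL8 at -1.07 ± 0.21. ICAM1 (-0.94 ± 0.19), LIF (-0.93 ± 0.24) and the TNF receptor TNFRSF1A (-1.08 ± 0.14) fell as well, while IL6 (-0.58 ± 0.23, adjusted p = 0.168), CCL2 (-0.45 ± 0.27), MMP1 (0.07 ± 0.23) and MMP3 (0.02 ± 0.27) did not pass. The glycosyltransferase GALNT15 (2.76 ± 0.37), CELF2 (2.48 ± 0.16), IGF1 (1.89 ± 0.29) and ANGPTL4 (1.75 ± 0.25) rose. In all, 406 genes were higher and 415 lower. With TNF+IL-17A at 6 h, edgeR passed 512 genes, 337 of them lower. Limma with the donor as a block, on only the compared libraries, called 78. PRG4 fell by 6.31, CXCL11 by 3.84, CXCL9 by 3.37, CXCL10 by 3.23, CXCL1 by 2.22 and CXCL8 by 1.88 on the log2 scale (SE 0.39, 0.73, 0.93, 0.66, 0.48 and 0.44). At this time 5 of 6 ELR CXC chemokines fell (5 adjusted over the list alone; camera adjusted p = 8.4e-06) and 4 of 14 other chemokines (6 adjusted over the list alone; 8.0e-05), and both calls held with an estimated correlation (0.0239 and 0.0267). Of the interferon response genes 8 of 27 fell (22 adjusted over the list alone; camera adjusted p = 1.1e-16), with adjusted p = 0.141 with an estimated correlation. The largest rise outside genes at 0 counts was that of the RNA-binding protein CELF2 (4.00 ± 0.42). Of the 15038 genes tested 5.46% passed in the mean and 3.40% at 6 h. Without donors 1, 2, 3 or 4 these became 2.29%, 14.6%, 1.32% and 1.54% in the mean and 1.05%, 8.14%, 1.43% and 1.47% at 6 h. Without the 5 libraries that stand apart 7.06% passed at 6 h. Of the genes named here as changed, CXCL1, CXCL8, ICAM1 and LIF in the mean and CXCL9 and CXCL8 at 6 h did not keep their call without every donor. Without those 5 libraries the chemokines with an ELR motif had a camera adjusted p of 0.0809 in the mean and 0.0663 at 6 h with an estimated correlation.

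LIFR siRNA lowered MMP1 to a fold of 0.156 of its control level (-2.68 ± 0.23, limma adjusted p = 7.0e-07). With it fell MMP3 (-1.50 ± 0.27), the monocyte chemokines CCL7 (-2.20 ± 0.31) and CCL8 (-1.87 ± 0.37), IL6 (-1.40 ± 0.23), CCL20 (-1.27 ± 0.25) and the hormone STC1 (-2.07 ± 0.29). SOCS3, a feedback inhibitor induced by STAT3, fell by 1.66 (SE 0.18), and the deiodinase DIO2 (-2.31 ± 0.31) and RASD1 (-2.10 ± 0.43) fell. Of the IL-17A-associated genes 5 of 22 fell (12 adjusted over the list alone; camera adjusted p = 2.9e-10), and of the IL-6 family genes 3 of 10, LIFR itself among them (6 adjusted over the list alone; 0.00685). The same held for 3 of 21 matrix-degrading enzymes and inhibitors, with 1 rise (6 adjusted over the list alone; 0.00648), and for 2 of 21 glycolysis genes (7 adjusted over the list alone; 1.0e-04). These 4 calls held with an estimated correlation. The IL-6 family list was not tested without LIFR, whose fall is that of the target itself. CXCL1 (-0.54 ± 0.28), CXCL8 (-0.62 ± 0.21, adjusted p = 0.115), LIF (-0.78 ± 0.24, adjusted p = 0.08) and ICAM1 (-0.55 ± 0.19) did not pass. The collagens COL15A1 (2.46 ± 0.30) and COL8A2 (1.68 ± 0.21), the enzyme DDAH1 (2.34 ± 0.20) and CELF2 (2.26 ± 0.16) rose. In all 497 genes passed, 310 of them higher. With TNF+IL-17A at 6 h 230 passed, of which 52.6% were higher. Limma with the donor as a block, on only the compared libraries, called 6. MMP1 (-3.03 ± 0.46), SOCS3 (-2.76 ± 0.50), MMP3 (-2.50 ± 0.69), CCL7 (-2.45 ± 0.51), CCL8 (-2.26 ± 0.56) and IL6 (-2.13 ± 0.38) fell. So did the interleukin 1 receptor antagonist IL1RN (-2.09 ± 0.47), the complement receptor C3AR1 (-3.64 ± 0.86) and the channel AQP9 (-3.78 ± 0.99). DDAH1 (3.44 ± 0.32), RASSF2 (3.53 ± 0.79) and CELF2 (3.86 ± 0.42) rose. Of the IL-17A-associated genes 3 of 22 fell at this time (11 adjusted over the list alone; camera adjusted p = 4.2e-10). Of all genes tested 3.30% passed in the mean and 1.53% at 6 h. Leaving out donors 1, 2, 3 or 4 gave 1.40%, 17.9%, 0.565% and 0.572% in the mean and 0.512%, 6.38%, 0.532% and 0.552% at 6 h. MMP3, CCL8, IL6, CCL20 and RASD1 in the mean and MMP3, CCL7, CCL8, IL1RN, C3AR1, AQP9 and RASSF2 at 6 h did not keep their call without every donor. The 5 libraries that stand apart left 760 and 690 genes when removed, and limma on log2(TPM + 1) split its calls as 416 higher and 74 lower in the mean.

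STAT3 siRNA shared many of these falls. MMP1 (-1.87 ± 0.23), DIO2 (-2.17 ± 0.31), SOCS3 (-1.41 ± 0.18), RASD1 (-1.83 ± 0.43) and CCL20 (-1.09 ± 0.25) fell, and MMP3 fell by 1.00 (SE 0.27). So did the oncostatin M receptor OSMR (-1.52 ± 0.19), the interleukin 1 receptor IL1R1 (-1.60 ± 0.22), the sphingosine receptor S1PR1 (-1.75 ± 0.26), the metalloreductase STEAP4 (-2.06 ± 0.41) and the complement factor CFB (-1.02 ± 0.15). In all, 91 genes were lower under both LIFR and STAT3 siRNA in the mean over conditions. That number was 0 in simulated data with the same shared controls and no effects, where noise was independent between genes. Without effects almost no calls are shared, so the 0 does not show what shared noise adds to real calls. Of independent lists 3.21 would be expected. Every other pair of siRNAs also shared more falls than expected, from 25 (CUX1 and LIFR, 5.16 expected) to 72 (STAT4 and ELF3, 5.31 expected). In the simulated data the effects of any pair of siRNAs over all genes correlated at 0.5. In the real data those of LIFR siRNA correlated at 0.7 with ELF3 siRNA and at 0.48 with STAT3 siRNA. Of the IL-17A-associated genes 6 of 22 fell and 1, ELF3 (0.70 ± 0.19, limma adjusted p = 0.0346), rose (9 adjusted over the list alone; camera adjusted p = 3.5e-06, and 0.00904 with an estimated correlation). Of the STAT3-associated genes 5 of 18 fell under STAT3 siRNA (9 adjusted over the list alone; camera adjusted p = 7.3e-05) and 2 of 18 under LIFR siRNA (9 adjusted over the list alone; 6.6e-06), with adjusted p = 0.114 and 0.0748 with an estimated correlation. IL6 (-0.22 ± 0.23), CXCL8 (-0.35 ± 0.21) and CXCL1 (-0.06 ± 0.28) did not pass. The actin-binding protein XIRP1 (3.64 ± 0.32), the antigen presentation genes HLA-DMB (2.69 ± 0.46) and CD74 (2.11 ± 0.36) and IGFBP5 (1.87 ± 0.22) rose in 4 of 4 donors. Of the interferon response genes 5 of 27 rose, such as GBP4 (1.68 ± 0.36) and IFIT2 (1.39 ± 0.32), with 9 adjusted over the list alone (camera adjusted p = 6.4e-09, adjusted p = 0.381 with an estimated correlation). In all, 367 genes were higher and 258 lower. After 6 h of TNF+IL-17A 203 passed, 81 of them lower. Limma with the donor as a block, on only the compared libraries, called 0. The falls included STAT3 (-4.38 ± 0.34), MMP3 (-2.87 ± 0.71), CCL20 (-2.46 ± 0.68), MMP1 (-2.18 ± 0.45), SOCS3 (-1.76 ± 0.46) and the kinase inhibitor PKIA (-2.60 ± 0.63). The rises included XIRP1 (3.91 ± 0.86), CELF2 (3.77 ± 0.42), the cardiac actin ACTC1 (3.16 ± 0.74) and the prolyl hydroxylase EGLN3 (3.34 ± 0.91). Of the IL-17A-associated genes 4 of 22 fell at this time (8 adjusted over the list alone; camera adjusted p = 1.2e-08), and of the zinc and metallothionein genes 3 of 15 (5 adjusted over the list alone; 1.0e-04). The genes that passed were 4.16% of those tested in the mean and 1.35% at 6 h. They became 3.10%, 12.6%, 0.871% and 0.718% in the mean without donors 1, 2, 3 or 4, and 0.831%, 6.09%, 0.372% and 0.346% at 6 h. The 7 libraries of donor 2 with STAT3 siRNA had 1.82% to 4.44% of counts mitochondrial and 13.52% to 15.26% in their top 10 genes. In the control libraries of that donor these ran from 0.41% to 1.27% and from 20.2% to 25.15%, and with STAT3 siRNA in the other donors from 0.79% to 1.70% and from 16.92% to 21.32%. Of the 7, 3 are among the 5 that stand apart. Without the 5 libraries 2.95% passed at 6 h, and limma on log2(TPM + 1) called 62 higher and 21 lower. A fit of only the STAT3 and control siRNAs passed 0 genes in the mean (limma, 927 at an unadjusted p under 0.05). Of the genes named here as changed MMP3, RASD1, CCL20, STEAP4, ELF3, HLA-DMB, CD74, GBP4 and IFIT2 in the mean and all but STAT3 and CELF2 at 6 h did not keep their call without every donor.

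Under STAT4 siRNA the prion protein PRNP fell to a fold of 0.101 of its control level (-3.31 ± 0.20, limma adjusted p = 3.9e-09). With it fell C5orf15 (-2.55 ± 0.20), the clotting initiator F3 (-2.18 ± 0.18), SLC35B2 (-2.17 ± 0.16), the DNA flap nuclease FEN1 (-2.11 ± 0.17) and FICD, an enzyme of the endoplasmic reticulum (-2.10 ± 0.11). Of the cell cycle genes 10 of 25 fell, such as BIRC5 (-1.35 ± 0.18), RRM2 (-1.31 ± 0.18) and PLK1 (-1.26 ± 0.17), and 0 rose (15 adjusted over the list alone; camera adjusted p = 4.0e-14), with adjusted p = 0.0969 with an estimated correlation. Of the interferon response genes 3 of 27 fell (15 adjusted over the list alone; camera adjusted p = 1.2e-11, adjusted p = 0.272 with an estimated correlation), HERC5 by 1.61 (SE 0.31). None of the chemokines with an ELR motif passed (1 adjusted over the list alone), with CXCL6 at -0.76 ± 0.23 (adjusted p = 0.0615) and CXCL8 at -0.53 ± 0.21. IL6 (-0.51 ± 0.23), LIF (-0.50 ± 0.24), MMP1 (-0.32 ± 0.23) and MMP3 (-0.14 ± 0.27) did not pass. H2BC12 (2.37 ± 0.16), ANGPTL4 (2.17 ± 0.25), ACTC1 (2.15 ± 0.33), DDAH1 (2.13 ± 0.20) and ELF3 (0.75 ± 0.19, limma adjusted p = 0.0239) rose. In all 285 genes were higher and 355 lower. After 6 h of TNF+IL-17A 273 passed, of which 49.8% were higher. PRNP (-3.39 ± 0.34) and SLC1A1, a glutamate transporter (-3.44 ± 0.73), were among the falls and ACTC1 (3.99 ± 0.74), CELF2 (3.54 ± 0.42) and ANGPTL4 (3.51 ± 0.51) among the rises. The phosphatase CDC25C, which starts mitosis, had 3 counts under STAT4 siRNA and 72 in control, a ratio of 18.9 (6.22 to 93.9). The target itself missed the threshold at this time (-2.17 ± 0.71, edgeR adjusted p = 0.0968, lower in 3 of 4 donors). Of the cell cycle genes 7 of 25 fell (12 adjusted over the list alone; camera adjusted p = 4.9e-08), with adjusted p = 0.0564 with an estimated correlation. In the mean 4.26% of the genes tested passed, and at 6 h 1.82%. Dropping donors 1, 2, 3 or 4 gave 1.93%, 9.80%, 1.16% and 0.811% in the mean and 1.52%, 6.32%, 0.825% and 0.751% at 6 h. A fit of only the STAT4 and control siRNAs passed 11 genes in the mean. The 7 libraries of donor 2 with STAT4 siRNA had 1.45% to 4.92% of counts mitochondrial (0.83% to 2.30% in the other donors). That at 4.92%, from unstimulated cells, is among the 5 that stand apart, and without these 3.57% passed at 6 h and 6.41% in the mean. HERC5 and ELF3 in the mean and CDC25C at 6 h did not keep their call without every donor. On the compared groups alone edgeR passed 0 genes at 6 h (292 at an unadjusted p under 0.05) and DESeq2 21.

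The libraries labelled ELF3 siRNA differed from control in genes that include 0 of the panel of 14 cytokines, chemokines, proteases and related genes read in every comparison. Their target was not shown to be lower than in control cells in the mean over conditions (-0.12 ± 0.19, limma adjusted p = 0.779), while it passed at 16 h of TNF+IL-17A over the 35 target tests alone (0.0237). The helicase DHX15 (-2.24 ± 0.24, limma adjusted p = 1.6e-05), ENY2 (-1.81 ± 0.21), PRNP (-1.77 ± 0.20), the actin-binding protein CALD1 (-1.57 ± 0.14), the decoy receptor TNFRSF11B, which restrains osteoclast formation (-1.57 ± 0.20), and TMBIM1 (-1.54 ± 0.14) fell. Of the glycolysis genes 5 of 21 fell, such as PGAM1 (-0.71 ± 0.14) and ENO1 (-0.60 ± 0.13), and 0 rose (5 adjusted over the list alone; camera adjusted p = 3.3e-04, and 0.0426 with an estimated correlation). Of the interferon response genes 2 of 27 fell (11 adjusted over the list alone; camera adjusted p = 1.3e-07, adjusted p = 0.432 with an estimated correlation). IL6 (-0.09 ± 0.23), CXCL8 (-0.26 ± 0.21), CXCL6 (-0.77 ± 0.23, adjusted p = 0.0677) and MMP1 (0.16 ± 0.23) did not pass. COL15A1 (2.53 ± 0.30), LMLN (2.34 ± 0.28), LOXL3 (2.12 ± 0.15), H2BC12 (2.03 ± 0.16) and the cartilage proteoglycan ACAN (1.66 ± 0.33) rose. In all 255 genes were higher and 225 lower. With both cytokines at 6 h 300 passed, of which 39% were higher. Limma with the donor as a block, on only the compared libraries, called 6. The chemokines CXCL11 (-3.15 ± 0.68), CXCL10 (-2.97 ± 0.65), CCL8 (-2.47 ± 0.56) and CCL7 (-1.73 ± 0.50) and the interferon-induced genes OASL (-2.81 ± 0.69) and IFIT1 (-2.58 ± 0.60) fell. That made 4 of 14 chemokines without an ELR motif (8 adjusted over the list alone; camera adjusted p = 3.1e-04, and 0.0439 with an estimated correlation) and 5 of 27 interferon response genes (17 adjusted over the list alone; camera adjusted p = 1.3e-15, adjusted p = 0.164 with an estimated correlation). COL15A1 (3.00 ± 0.37) and CELF2 (3.47 ± 0.42) rose. Of those tested 3.19% passed in the mean and 1.99% at 6 h. With donors 1, 2, 3 or 4 left out the mean gave 0.878%, 17.3%, 0.572% and 0.565%, and 6 h gave 0.372%, 7.55%, 0.632% and 0.751%. Without the 5 libraries that stand apart 916 and 831 genes passed. PGAM1, ENO1 and ACAN in the mean and CXCL11, CXCL10, CCL8, CCL7, OASL and IFIT1 at 6 h did not keep their call without every donor. With limma on log2(TPM + 1) the split was 221 higher and 78 lower in the mean and 71 and 37 at 6 h.

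**Figure D3:**
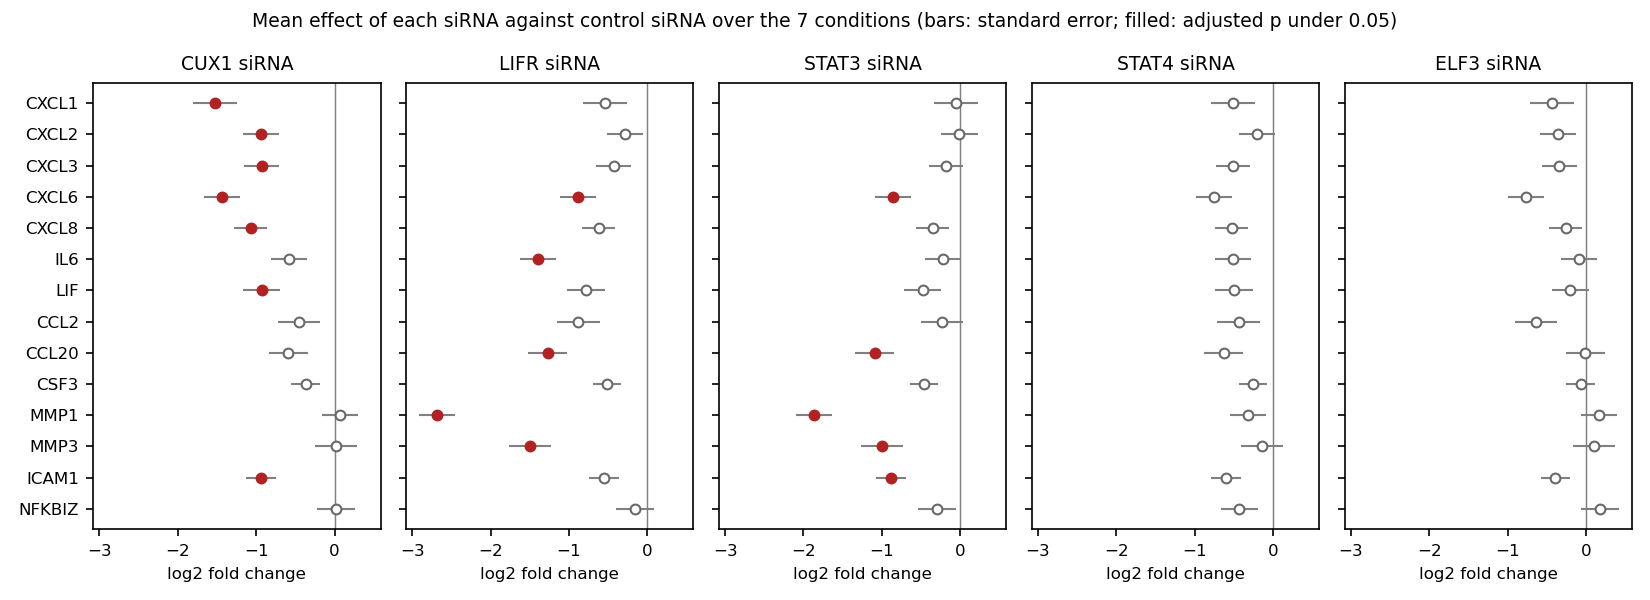
Log2 fold change (x axes) of 14 cytokine, chemokine, protease and related genes (y axis) under each siRNA against control siRNA in the mean over the 7 conditions; points are fitted values with SE bars, filled where the limma adjusted p is under 0.05. CUX1 siRNA lowered CXCL1 by 1.52 and CXCL8 by 1.07, LIFR siRNA lowered MMP1 by 2.68 and IL6 by 1.40, and STAT3 siRNA lowered MMP1 by 1.87 (log2).

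**Figure D4:**
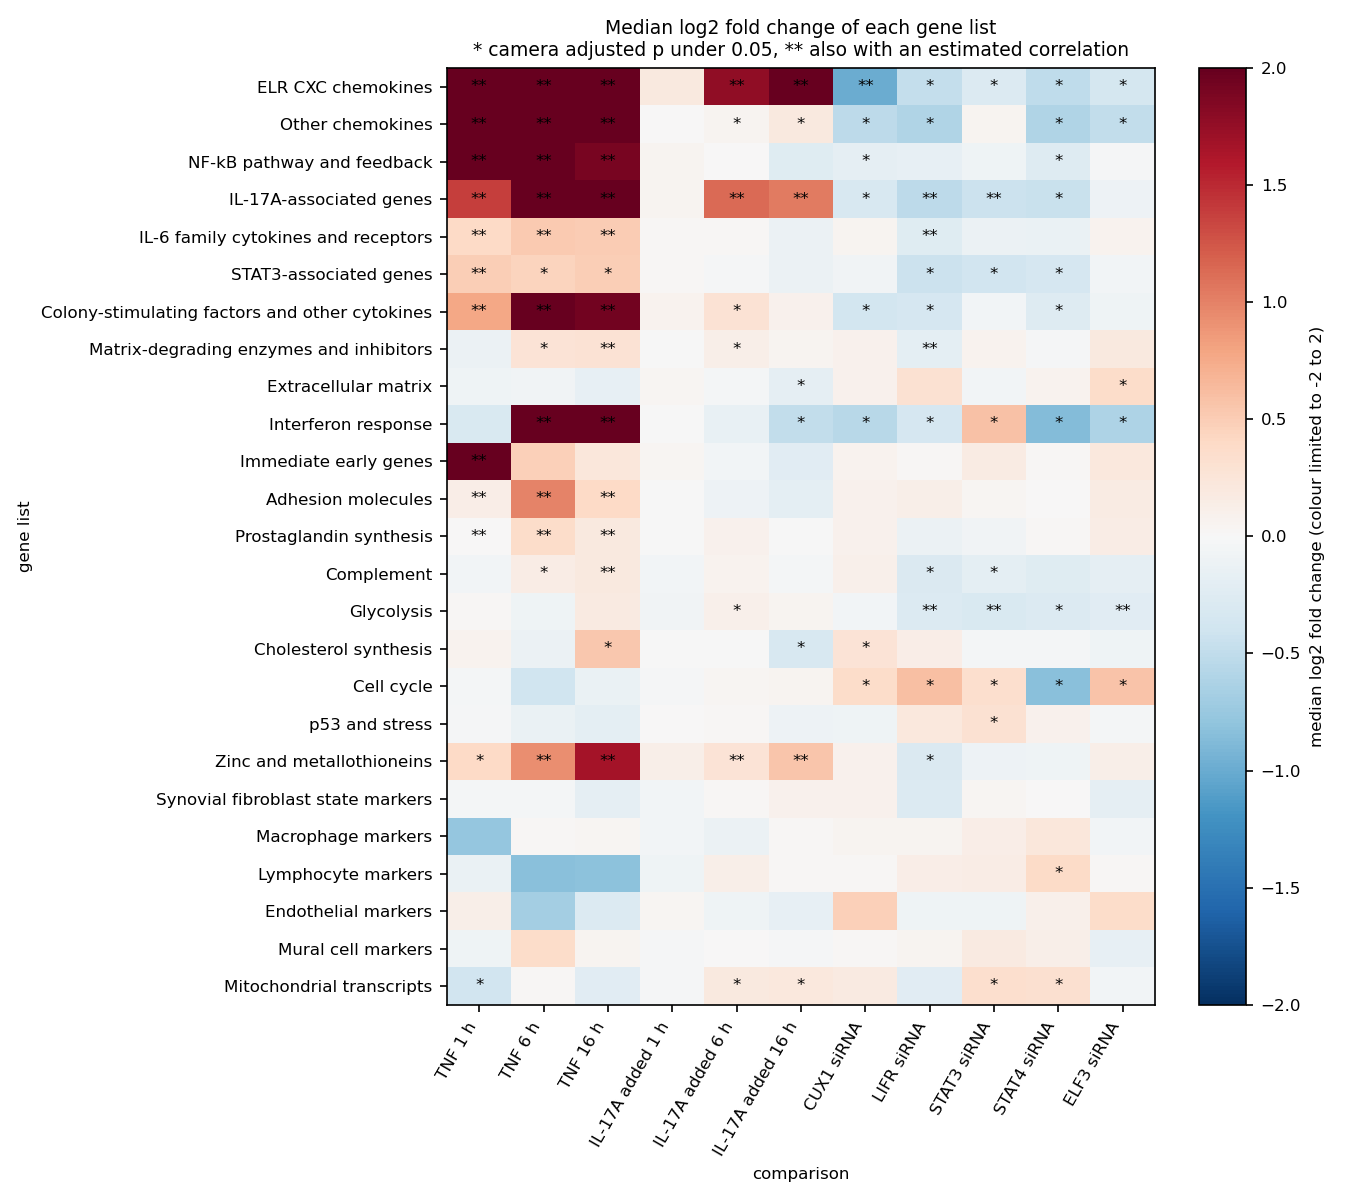
Median log2 fold change (colour, limited to -2 to 2) of each of 25 gene lists (y axis) in 11 comparisons (x axis); stars mark a camera adjusted p under 0.05, and double stars one that also held with an estimated correlation. The IL-17A-associated list was lower under LIFR siRNA (camera adjusted p = 2.9e-10) and STAT3 siRNA (3.5e-06) with double stars.

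Whether an siRNA changed the effect of adding IL-17A was tested directly, as the difference between the IL-17A effects under the siRNA and under control siRNA, averaged over 6 and 16 h. None of the panel genes passed under any of the 5 siRNAs. The changes for CXCL1 ran from -0.95 ± 0.48 (STAT4 siRNA) to 0.09 ± 0.47 (STAT3 siRNA), those for IL6 from -0.61 ± 0.38 (STAT4 siRNA) to 0.17 ± 0.37 (CUX1 siRNA), and that for CXCL3 was -0.99 ± 0.46 under LIFR siRNA (edgeR adjusted p = 0.958). Of the IL-17A-associated genes 0 of 22 passed under LIFR siRNA, but the list as a whole was lower (0 adjusted over the list alone; camera adjusted p = 2.4e-05, and 0.0165 with an estimated correlation). The same list was lower under STAT4 siRNA (camera adjusted p = 5.6e-04) with adjusted p = 0.0555 with an estimated correlation, and under STAT3 siRNA (0.00813) with adjusted p = 0.164 with an estimated correlation. Mitochondrial transcripts, which were high in the control library that stood apart at 16 h, were lower in this difference under LIFR siRNA (camera adjusted p = 7.3e-05, adjusted p = 0.493 with an estimated correlation). For CUX1 siRNA edgeR passed 0 genes, with 673 at an unadjusted p under 0.05. For the LIFR, STAT3, STAT4 and ELF3 siRNAs it passed 1 gene each. In each case it was KPNA2P2, a processed pseudogene of the importin gene KPNA2 (-2.34 ± 0.48, -2.65 ± 0.48, -2.84 ± 0.49 and -2.56 ± 0.48; adjusted p = 0.0496, 0.00337, 8.4e-04 and 0.00731). At an unadjusted p under 0.05 there were 730, 742, 630 and 706 genes (limma on log2(TPM + 1) and edgeR on the compared groups alone passed 0 for each of the 5, and DESeq2 on them 1, 1, 0, 3 and 0). KPNA2P2 was named for 3 of these siRNAs after its values were seen, its reads can be shared with KPNA2, and in control cells its IL-17A effect at 16 h exceeded that at 6 h by 5.97 ± 0.73. Without the 5 libraries that stand apart its changes were 0.42, -0.04, -0.06 and 0.21, and no gene passed under any of the 5 siRNAs. The IL-17A-associated list under LIFR siRNA had a camera adjusted p of 2.3e-04, and of 0.0618 with an estimated correlation. Without donor 1 or donor 3 edgeR passed 0 genes for each siRNA. Without donor 4 it passed 0, 1, 2 and 0 for LIFR, STAT3, STAT4 and ELF3 siRNA. Without donor 2 it passed 3, 3 and 2 for the last 3 of these, and 0.858% of genes for LIFR siRNA.

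Markers of other cell types were read for changes, and their levels are not given here. Of the lists of macrophage, lymphocyte, endothelial and mural cell markers, none passed in the TNF and IL-17A comparisons. Of the siRNA comparisons 1 passed, the lymphocyte markers under STAT4 siRNA in the mean over conditions (0 of 5 genes passed, 3 adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.103 with an estimated correlation). Single members passed in both directions. Of the endothelial genes VWF and CDH5 fell after 16 h of TNF, VWF from 36 counts to 0 (at least 7.01-fold lower) and CDH5 by 3.05 (SE 0.84), while TEK rose (1.62 ± 0.53). In the mean over conditions CDH5 rose under CUX1 siRNA (1.03 ± 0.27) and PECAM1 fell under LIFR siRNA (-0.85 ± 0.23). At 6 h of TNF+IL-17A ERG rose under CUX1, STAT4 and ELF3 siRNA (1.34 ± 0.28, 1.00 ± 0.29 and 1.07 ± 0.28). The B cell gene CD79B rose under CUX1 siRNA in the mean (1.41 ± 0.20) and at that time, with 34 counts against 2, a ratio of 17.4 (at least 4.45). CD14, a receptor for bacterial lipopolysaccharide that fibroblasts also express, fell under STAT4 siRNA (-0.90 ± 0.21 in the mean and -1.59 ± 0.40 at 6 h of both cytokines) and ELF3 siRNA (-0.83 ± 0.21 and -1.40 ± 0.38). The macrophage marker CD68 fell at 6 h under CUX1 (-0.69 ± 0.21) and LIFR siRNA (-0.72 ± 0.21), and the mural marker CSPG4 fell with IL-17A at 16 h in the mean over siRNAs (-0.66 ± 0.18). SELE, which endothelium expresses and which was listed with the adhesion molecules, fell under CUX1 siRNA (-0.88 ± 0.21 in the mean, and from 34 counts to 1 at 6 h, a ratio of 33.3, 5.58 to 1350). Of all these only CD79B under CUX1 siRNA in the mean kept its call whichever donor was left out.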

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

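The simulation of libraries without siRNA effects, the shares of genes lower per library of STAT3 siRNA, the tests without the 5 libraries that stand apart, those with the GC content and length trend removed and those against other targeting siRNAs were chosen after the results they bear on were seen, and the splits of the samples were planned.

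For IL-17A at 16 h, 461 genes were higher in control cells and 746 were lower in the mean over the 6 siRNAs. A library that stands apart, the control library of donor 3, is a candidate source of the 461: their median IL-17A effect was 0.97 in control cells and 0.23 under the 5 targeting siRNAs (-0.01 to 0.68 per siRNA), and 8 of them still passed without the 5 libraries that stand apart. The tables argue against these libraries and against GC content or transcript length as the whole cause of the 746 falls, of which 546 were still called lower without the 5 libraries and 618 with the trend removed (median -0.66 before and -0.59 after). Of the 208 rises, 78 were still called higher without the 5 libraries. An effect of IL-17A itself stays open as an untested explanation of the falls, and so does handling of the wells of that time, since the labels give no order of wells.

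The 68 genes higher under each of the 5 siRNAs may reflect the libraries they share as a reference. Noise in the shared control libraries was simulated as independent between genes. In each of 50 such data sets without siRNA effects 0 genes were called under all 5 siRNAs. These data gave almost no shared calls for any pair of siRNAs (at most 0.02 rises in the mean). The 0 therefore cannot show how many genes such noise adds where siRNAs have effects. A deviation of a control library that many genes share was not simulated and stays open. GC content or transcript length as the whole cause is argued against by the 62 genes still called with the trend removed. A candidate explanation is that the control siRNA lowers these genes. The spread among the 5 targeting siRNAs lay in the median at percentile 33.4 among genes of like level (quartiles 17.2 and 62.6). This spread cannot decide the question, because genes chosen for rises under all 5 siRNAs are more likely to have a small one. Without cells that had no siRNA, a rise under all 5 siRNAs and a fall under the control siRNA give the same values, so a common effect of the targeting siRNAs stays open.

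A shared pathway of LIFR and STAT3 could explain the 91 genes lower under both siRNAs, of which 85 were still lower under both with the GC content and length trend removed, 36 against the mean of CUX1, STAT4 and ELF3 siRNA, and 12 against the mean of the other 4, which holds the other siRNA of the pair. Noise in the shared control libraries as the whole cause is argued against by 342 genes lower under LIFR siRNA in donors 3 and 4: in 13 of 13 pairs of STAT3 siRNA and control libraries of donors 1 and 2 more of them were lower than of all genes, by 16.8 percentage points in the mean (SD 9.55, from 20.1 to 28.8 in donor 1 and from 2.57 to 21 in donor 2). Over these 2 donors 76.9% of them were lower under STAT3 siRNA (49.2% of all genes) and 64.6%, 74.3% and 74% under CUX1, STAT4 and ELF3 siRNA, but the 80% in both directions set beforehand was not met, and the reverse split was empty, since 0 genes passed for LIFR siRNA in donors 1 and 2 (limma, 551 at an unadjusted p under 0.05). A response common to all siRNAs was read from the other 3 siRNAs, under which the median change of the 91 genes was -0.36, against -0.92 under LIFR and STAT3 siRNA. Every other pair of siRNAs shared falls too, up to 72 genes for STAT4 and ELF3 siRNA. A shared pathway and a response common to all siRNAs cannot be told apart, because the medians under the other siRNAs lie between none and a like change (-0.16, -0.52 and -0.4 under CUX1, STAT4 and ELF3 siRNA) and single genes differ, MMP1 at 0.07, -0.32 and 0.16 and ADAM19 at 0.39, -1.5 and -1.09.

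Other splits of the samples were compared with the real ones by limma with the donor as a block. Since the samples pair by donor, only the 8 splits that part the samples of every donor, as the real one does, are comparable with it, and they are too few for a share under 0.125. For TNF at 1, 6 and 16 h the real split gave 284, 1985 and 1985 genes and the highest other of the 8 gave 0. For IL-17A in control cells it gave 5 at 6 h (highest other 0), and in the mean over siRNAs 6, 54 and 1028 at 1, 6 and 16 h (highest other 1, 0 and 0). For CUX1, LIFR and ELF3 siRNA it gave 78, 6 and 6 genes at 6 h of TNF+IL-17A, and for CUX1, LIFR, STAT4 and ELF3 siRNA 1505, 579, 9 and 447 in the mean over conditions (highest other 0 for each). In each of these 1 split of the 8, the real one, gave as many. Where the real split gave 0 genes the count of splits decides nothing, since all 8 of 8 then give as many. That was so for IL-17A in control cells at 1 and 16 h, STAT3 and STAT4 siRNA at 6 h, STAT3 siRNA in the mean over conditions and the 5 changes of the IL-17A effect (highest other 0, and 1 for the change under STAT3 siRNA). The other splits, 35 in all with the 8, leave both samples of some donors on one side, and 3 of them could not be fitted. Some of them called more genes than the real split. Where the real split gave 0 they called up to 3951 for IL-17A in control cells at 16 h and 1533 and 1576 for STAT3 siRNA at 6 h and in the mean. Against real counts of 6, 579 and 447 they called up to 150 for the mean effect of IL-17A at 1 h and 1563 and 1344 for LIFR and ELF3 siRNA in the mean. This points to a structure of the samples, of which the source was not tested.

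Of 297 sets of 4 donor values behind the named results, 18 had a donor far from the other 3, where chance gives 1 in 20 (14.8). In donor 1 ELF3 under its own siRNA was at 0.27 in the mean over conditions (others -0.27 to -0.21). With TNF, NR4A1 at 1 h was at 3.80 in donor 3 (5.52 to 5.72), and IDO1 at 6 h at 6.13 in donor 3 (8.22 to 8.52). At 16 h of TNF, CYP1A1 was at -4.66 in donor 1 (-1.11 to -0.57) and ABCA8 at -2.01 in donor 3 (-3.16 to -3.03). JUNB, for IL-17A in the mean over siRNAs at 16 h, was at -1.29 in donor 1 (-2.03 to -1.92). Under CUX1 siRNA in the mean, IGF1 was at 2.91 in donor 1 (1.50 to 1.57). STAT3 siRNA left XIRP1 at 2.67 in donor 1 in the mean (3.87 to 4.04) and MMP1 at -3.29 in donor 3 at 6 h of TNF+IL-17A (-1.96 to -1.89). STAT4 siRNA had LIF at -1.26 in donor 2 in the mean (-0.33 to -0.18), and STAT4 itself at -5.49 in donor 3 at 6 h of TNF (-2.81 to -2.37). ELF3 siRNA had TMBIM1 at -1.91 in donor 1 in the mean (-1.42 to -1.40). LIFR siRNA had CD68 at -1.22 in donor 1 at 6 h of TNF+IL-17A (-0.58 to -0.48). CD14 under ELF3 siRNA was at -1.44 in donor 1 in the mean (-0.68 to -0.54) and at -2.40 there at 6 h of TNF+IL-17A (-0.98 to -0.80). At that time ELF3 siRNA had CCL8 at -4.77 (-1.77 to -1.51) and CELF2 at 2.94 (3.33 to 3.37), both in donor 1. ELF3 under its own siRNA at 16 h of TNF was at 1.17 in donor 2 (-0.98 to -0.70).

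The pseudogene KPNA2P2 differed between siRNAs by the test of the difference itself: its IL-17A effect was lower than in control cells under LIFR (-2.34), STAT3 (-2.65), STAT4 (-2.84) and ELF3 siRNA (-2.56), and without the 5 libraries that stand apart the differences were 0.42, -0.04, -0.06 and 0.21.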

How the results depend on the processing

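The tests on all 192 libraries, without the 5 libraries that stand apart, with the GC content and length trend removed and against the mean of the other 4 siRNAs were chosen after the data were seen, and the other tests were planned and all ran. Results are given here as the number of passing genes in percent of the 15038 genes tested, so that 1 gene is 0.00665%. The main values for TNF at 1, 6 and 16 h were 1.20%, 10.1% and 7.37%. For IL-17A in control cells they were 0, 0.0532% and 3.24%, and in the mean over siRNAs 0, 0.0931% and 6.34%. The CUX1, LIFR, STAT3, STAT4 and ELF3 siRNAs had 3.40%, 1.53%, 1.35%, 1.82% and 1.99% at 6 h of TNF+IL-17A and 5.46%, 3.30%, 4.16%, 4.26% and 3.19% in the mean over conditions. The change of the IL-17A effect had 0 genes for CUX1 siRNA and 0.00665% for each of the other 4. Of the other values of these numbers, of the targets and of the gene lists, 190 stayed within 1.5 times the main one and 208 did not. Where no cause is given below, the cause was not tested.

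RLE scaling and removal of the GC content and length trend left every total number of passing genes within 1.5 times the main one, though not the split into higher and lower for IL-17A in the mean at 16 h. The total also stayed within 1.5 times with a prior count of 0.5 and with unstimulated wells kept separate, where these were run. IL-17A in control cells at 1 h gave 0 genes with each setting (265 at an unadjusted p under 0.05 with edgeR in the main test). TNF stayed within 1.5 times at each time without the 5 libraries that stand apart, with all 192 libraries and without the low-count filter. RLE, the missing filter and the removed trend shifted the median log2 fold change of all genes by no more than 0.09.

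That median shifted further with limma on log2(TPM + 1), which has no scaling between libraries beyond TPM. The shift was -0.29 for IL-17A in control cells at 16 h and, at 6 h of TNF+IL-17A, 0.12, 0.19, 0.14 and 0.15 under CUX1, LIFR, STAT3 and ELF3 siRNA. It was 0.14 and 0.11 for LIFR and ELF3 siRNA in the mean over conditions, and 0.15, 0.16, 0.10 and 0.16 for the change of the IL-17A effect under CUX1, LIFR, STAT4 and ELF3 siRNA. With this test 0.791%, 6.22% and 4.84% of genes passed for TNF at 1, 6 and 16 h, and 4.95% for IL-17A in control cells at 16 h. For CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA 1.30%, 0.884%, 0.552%, 0.798% and 0.718% passed at 6 h of TNF+IL-17A. For CUX1, STAT3, STAT4 and ELF3 siRNA 3.26%, 2.34%, 1.94% and 1.99% passed in the mean over conditions. The change of the IL-17A effect under LIFR, STAT3, STAT4 and ELF3 siRNA gave 0 genes (4.18% to 5.13% at an unadjusted p under 0.05).

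Without the low-count filter 1.97%, 0.964%, 0.878%, 0.984% and 1.06% passed for CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA at 6 h of TNF+IL-17A. In the mean over conditions 3.36%, 1.99%, 2.33%, 2.38% and 1.86% passed for the same siRNAs. IL-17A in the mean over siRNAs at 1 h gave 0.00665%, and the change under LIFR siRNA gave 0 genes (edgeR, 7.99% at an unadjusted p under 0.05).

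With no donor block the pairing of libraries by donor is ignored. Then 0.446%, 4.56% and 2.61% passed for TNF at 1, 6 and 16 h, 0.0199% for IL-17A in control cells at 6 h, and 0.0266% and 0.592% for IL-17A in the mean over siRNAs at 6 and 16 h. For CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA 0.725%, 0.166%, 0.180%, 0.326% and 0.253% passed at 6 h of TNF+IL-17A and 0.698%, 0.120%, 0.153%, 0.186% and 0.186% in the mean over conditions. The change under LIFR, STAT3, STAT4 and ELF3 siRNA gave 0 genes (edgeR, 2.07% to 2.89% at an unadjusted p under 0.05). Each gene in these numbers had also passed with the block, and the missing block moved no other number by more than 1.5 times.

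Leaving out each donor in turn gave 0.605% to 1.26%, 4.86% to 11.7% and 3.80% to 10.0% for TNF at 1, 6 and 16 h, lowest without donor 4. IL-17A in control cells ranged over 0 to 0.0532% and 0.0133% to 11% at 6 and 16 h, lowest without donor 3, and in the mean over siRNAs over 0 to 0.00665%, 0.0133% to 0.0399% and 2.77% to 10.6% at 1, 6 and 16 h. The ranges for CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA were 1.05% to 8.14%, 0.512% to 6.38%, 0.346% to 6.09%, 0.751% to 6.32% and 0.372% to 7.55% at 6 h of TNF+IL-17A. They were 1.32% to 14.6%, 0.565% to 17.9%, 0.718% to 12.6%, 0.811% to 9.80% and 0.565% to 17.3% in the mean over conditions, and each of these 10 was highest without donor 2, from whom 4 of the 5 libraries that stand apart came. The change under LIFR, STAT3, STAT4 and ELF3 siRNA ranged over 0 to 0.858%, 0 to 0.0199%, 0 to 0.0199% and 0 to 0.0133%. Where the lowest was 0 genes, 1.80% to 6.35% had an unadjusted p under 0.05 (edgeR). For IL-17A in control cells at 16 h MT-ND3 ranged from -0.36 without donor 3 to 3.66, and for the change under STAT3 siRNA KPNA2P2 ranged from -3.08 to 0.04 without donor 3, so both reversed there.

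The 2 donors of plate 2 alone, a smaller set of libraries, gave 0.346%, 2.20% and 1.44% for TNF at 1, 6 and 16 h. IL-17A gave 0 and 0.00665% in control cells and 0.0133% and 1.44% in the mean over siRNAs, at 6 and 16 h. For CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA they gave 0.286%, 0.0532%, 0.0465%, 0.153% and 0.0665% at 6 h of TNF+IL-17A and 0.0133%, 0, 0.0133%, 0.00665% and 0 in the mean over conditions. The change under LIFR, STAT3, STAT4 and ELF3 siRNA gave 0 genes, and beside the zeros 1.60% to 4.45% had an unadjusted p under 0.05 (edgeR and limma). Of the 5 targets 2 passed, against 4. MT2A (-0.57) and MT-ND3 (-1.06) reversed here for IL-17A in control cells at 16 h, as did KPNA2P2 for the change under LIFR (0.17), STAT3 (0.42) and ELF3 siRNA (0.22). The 2 donors of plate 1 alone gave 8.80% for IL-17A in control cells at 16 h, and 0.00665% and 0.0266% for IL-17A in the mean over siRNAs at 1 and 6 h. They gave 1.78% and 0.652% for CUX1 and ELF3 siRNA at 6 h of TNF+IL-17A, and 5.64% and 7% for LIFR and STAT3 siRNA in the mean over conditions. The change under LIFR, STAT3 and ELF3 siRNA gave 0 genes (edgeR, 5.35% to 6.48% at an unadjusted p under 0.05).

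On only the compared groups the spread is estimated from fewer libraries. There the wells of other conditions, which share a transfection with those compared, do not enter the estimate. Which of these lowered the numbers was not tested. There edgeR gave 2.97% and 14.4% for TNF at 1 and 16 h and 0.160% and 0 for IL-17A in control cells at 6 and 16 h. With CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA it gave 0.891%, 0.106%, 0.00665%, 0 and 0.0931% at 6 h of TNF+IL-17A. For the change under LIFR, STAT3, STAT4 and ELF3 siRNA it gave 0 genes, and beside the zeros 1.09% to 3.43% had an unadjusted p under 0.05. DESeq2 on the same libraries gave 3.58% and 14.6% for TNF at 1 and 16 h, 0.233% and 0.0864% for IL-17A in control cells at 6 and 16 h, and 0.512% and 0.14% for STAT3 and STAT4 siRNA at 6 h. For the change it gave 0.00665% and 0.0199% under CUX1 and STAT4 siRNA and 0 genes under STAT3 and ELF3 siRNA (1.84% to 3.76% at an unadjusted p under 0.05).

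In the mean over conditions, a fit of only the siRNA and the control gave 10.4%, 0 and 0.0731% for CUX1, STAT3 and STAT4 siRNA, and 2 of the 5 targets passed. For STAT3 siRNA 6.16% had an unadjusted p under 0.05 in that fit (limma). The 6 stimulated conditions alone gave 2.77% for STAT4 siRNA, and edgeR on counts summed per donor gave 5.46% for ELF3 siRNA. Against the mean of the other 4 siRNAs 1.12% and 1.92% passed for LIFR and ELF3 siRNA, and MMP1 reversed under STAT4 siRNA (0.75). Of the 600 tests of gene lists 27.2% passed with the preset correlation, and 10.8%, all of them among the former, with an estimated one. Without the 5 libraries that stand apart 25.2% passed, and 23% were among the former with the same direction.

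Without those 5 libraries 0.0665% of genes (10 genes) passed for IL-17A in control cells at 16 h, where 1 library of 3 was removed. In cells given CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA 7.06%, 4.59%, 2.95%, 3.57% and 5.53% passed at 6 h of TNF+IL-17A, and for LIFR, STAT4 and ELF3 siRNA 5.05%, 6.41% and 6.09% in the mean over conditions. The change under LIFR, STAT3, STAT4 and ELF3 siRNA gave 0 genes (edgeR, 2.23% to 5.01% at an unadjusted p under 0.05). MT-ND3 reversed for IL-17A in control cells at 16 h (-0.53), as did KPNA2P2 for the change under LIFR (0.42) and ELF3 siRNA (0.21). With all 192 libraries 0.00665%, 0.0532% and 4.05% passed for IL-17A in the mean over siRNAs at 1, 6 and 16 h, where MT-CO3 reversed at 16 h (-0.07). CUX1, LIFR, STAT4 and ELF3 siRNA gave 3.03%, 2.15%, 2.28% and 1.62% in the mean over conditions, and the change under LIFR, STAT3 and ELF3 siRNA 0 genes (edgeR, 4.34% to 4.88% at an unadjusted p under 0.05).

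Of the 295 results of single genes named in the text 258 had passed. Of these 48 kept their call and direction in each setting run for them, and 53.5% whichever donor was left out. Over the 4770 other values of single genes, 3778 kept side and direction, 918 kept the direction and no longer passed, and 33 passed newly in the same direction. Another 29, which had not passed, changed sign by more than their SE, and the 12 reversals are those above. The low-count filter kept 15038 of 31487 genes, and how many of the others were lost to depth was not tested.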

Other observations

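The test of CUX1 transcripts was chosen after the main results were seen. CUX1 makes protein-coding transcripts with different 3' ends, and CUX1 siRNA left different shares of them over the conditions that a donor had under both siRNAs. Of the estimated counts of the 3 transcripts that end with the exon of the homeodomain form 24.6% ± 5.82 were left (SD, n = 4), and of the 6 that end further downstream 1.07% ± 1.03 (SD, n = 4). Both shares were under 100% in 4 of 4 donors, and the split of reads between transcripts is an estimate of kallisto.

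Whether an siRNA effect at 6 h of TNF+IL-17A differed from the effect in unstimulated cells was tested as a difference. This test and those of the IL-17A effect between times were outside the design, and were set up with the main comparisons before their results were seen. For CUX1, LIFR, STAT3, STAT4 and ELF3 siRNA edgeR passed 0 genes, with 326, 260, 335, 484 and 294 at an unadjusted p under 0.05, and no other tool was run. The IL-17A effect in control cells at 6 h minus that at 1 h gave 0 genes (322 at an unadjusted p under 0.05). That at 16 h minus that at 6 h gave 6, all higher: KPNA2P2 (5.97 ± 0.73 SE), PABPC1 (1.88 ± 0.37), SEC62 (1.44 ± 0.30), NEXN (2.06 ± 0.46), ANKRD34A (2.60 ± 0.58) and 1 gene without a symbol. This difference rests on 3 donors with TNF+IL-17A at 16 h, and the control library of donor 3 stands apart. It was not tested without that library, so a late effect of IL-17A cannot be told from a deviation of that library.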
